A study of Mus musculus with 12 samples.

How the data were processed

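RNA was measured by sequencing in 12 libraries from the duodenum of C57BL/6N mice, in 4 groups of 3: Chow, HFD (high-fat diet), HFD Vehicle and HFD PCN. Per the labels' protocols, mice entered the diets at 6 weeks of age and stayed on them for 18 weeks. The HFD PCN mice then received pregnenolone 16α-carbonitrile (PCN), a ligand of the rodent pregnane X receptor (PXR), at 50 mg/kg by intraperitoneal injection once a day for 4 days, and the HFD Vehicle mice received 30% DMSO in corn oil. Total RNA was treated with DNase and made into Illumina libraries, per the labels' protocols. The extraction protocol names pieces of liver, whereas the tissue label of each sample is duodenum. For this reason a list of hepatocyte markers was checked in each library. Each library has a number of its own, and nothing else in the labels says that they came from separate animals. The p-values may therefore measure only the spread between these samples.

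The authors deposited 2 tables of raw read counts per gene, of 6 libraries each, with their own comparison beside the counts. The first holds Chow and HFD and the second HFD Vehicle and HFD PCN. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with GRCm38 (mm10), without versions. The annotation release, the strand setting of the counting and the read filters were not given in the sources used here. The tables list 28066 and 28731 genes, of which 26121 stand in both, and every listed gene had a total of at least 1 count in its table. A gene missing from a table was treated as not measured there and never as 0, since genes in only 1 table had total counts of up to 1291573. Gene symbols were found for 28023 and 28688 of the listed identifiers. Coordinates are those of GRCm38 as in the deposited tables, counted from 1. They were the same as in GENCODE release M21 for 26849 and 27497 genes. No column of values was left without a sample. The authors' comparison columns hold a log2 fold change, a p-value and an adjusted p-value per gene, which were used only where the authors' deposited table is named.

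Total counts ranged from 4676718 (HFD Vehicle 55) to 20684369 (HFD PCN 5), with a median of 15404357. Replicate libraries of a group differed by more than sampling noise in each pair, with a chi-square per degree of freedom of 30.5 to 213 and correlations of log2 CPM of 0.895 to 0.982. Each library counted as 1 replicate because the labels give it a number of its own. CPM (counts scaled to 1000000 per library) given by group were computed from the deposited counts after TMM scaling within each comparison, so that levels from different comparisons were scaled apart. CPM of single libraries for Vil1, Fabp1, Alb, Cps1 and heat shock genes, and shares of counts, were taken over the library's total in its own table, without TMM. List scores and correlations between libraries used TMM over all 12 libraries, on genes in both tables.

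The test was chosen before the data were examined, as were the alternatives, the gene lists and the rule for naming genes, except where a choice is said to have been made later. Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors and the robust quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F, which is approximate. HFD against Chow and HFD PCN against HFD Vehicle were the main comparisons. HFD Vehicle against HFD joined raw counts of both tables. It shares its libraries with the main comparisons, and the HFD Vehicle libraries enter it and the PCN comparison with opposite sign.

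A set of 43 gene lists of pathways and cell types was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 3 measured members. Beside it stood camera with an estimated correlation, and fry, which tests whether the genes of a list move one way without comparing them with other genes. For each list the number of members passing was also counted with p adjusted over the list alone. The genes called lower on the diet were tested in the PCN comparison with fry.

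Named genes were taken by this rule. In each comparison they were the up to 6 called genes with the largest rise and the 6 with the largest fall that had a mean of at least 20 counts and no overlap between groups, leaving out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. To these were added up to 4 called members of each list, the 2 members with the smallest p of each list called by camera without a called member, and a fixed set of genes of PXR and lipid biology in every case, among them Nr1i2, Nr1i3, Cyp3a11, Abcb1a, Cyp2b10, Npc1l1 and Cpt1a. Some genes that the rule names are not reported here. The plan was to take lists in the order of their camera p. The text departs from it: lists are grouped by theme, and some were left out although lists with a larger p were kept.

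Alternatives were other size factors, other filters on low counts, DESeq2 1.42.0, limma-voom, a fit of all 12 libraries, a minimum fold change of 1.5, leaving out the pancreatic acinar list, leaving out each library in turn, untreated HFD as the control of PCN, an estimated correlation and other factors for the lists. After the data were seen, these were added: leaving out genes that resemble ribosomal RNA, library quality weights, leaving out HFD Vehicle 23 and 50 together, the list tests with untreated HFD as the control, and, for the correlation of diet and PCN fold changes and the enterocyte scores, leaving out libraries. The alternatives on pseudocounts, planned in case the values had been normalized, did not apply. Figures were drawn with matplotlib 3.10.9.

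The tests were tested on simulated data, with counts drawn from the means and library sizes of the real libraries and known changes. With a spread simulated gene by gene, 48.5% of the genes changed 2-fold in the diet comparison (47 of 97) and 98 of the 100 changed 8-fold were called, over 15044 genes. In the PCN comparison, over 15803 genes, 13 of 100 and 93 of 95 were called, and in the vehicle comparison, over 15916 genes, 15 of 94 and 89 of 92. False calls made up 13.2%, 8.62% and 7.96% of all calls in this simulation. They made up 4.43%, 3.23% and 5.83% with a spread drawn from the trend over expression. A 2-fold change was thus often missed at the spread between the PCN and Vehicle libraries. With no gene changed, camera called 0, 1 and 0 lists in the diet, PCN and vehicle comparisons. The simulated genes were drawn independently of each other, so these counts cannot show how often camera calls lists of correlated genes. In the real libraries the estimated correlation of the PXR target list was 0.374 in the diet and 0.675 in the PCN comparison. With the PXR target list doubled, camera called that list in each of the 3, while with an estimated correlation its adjusted p was 0.00152, 0.0756 and 0.00539.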

Results

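RNA from the duodenum was sequenced in 3 libraries each of Chow, HFD, HFD Vehicle and HFD PCN mice, at 4676718 to 20684369 counts per library. The duodenal brush border gene Vil1 stood at 912 to 2489 CPM and Fabp1, the fatty acid binding protein shared by liver and proximal gut, at 296 to 2268 CPM. Albumin (Alb), the main secreted product of hepatocytes, stood at 0.104 to 1.11 CPM, and the hepatocyte marker list took 0.0643% to 0.121% of the counts. Its member Cps1 alone made up nearly all of that share, at 637 CPM in HFD 30 (lowest share) and 1203 CPM in HFD PCN 27 (highest share). The share therefore says little about the other hepatocyte markers. Mitochondrial ribosomal RNA took 33.6% of the counts of HFD Vehicle 23 and 8.69% to 19.2% of those of the other libraries. The chaperone gene Hsp90aa1 stood at 1427 CPM in HFD Vehicle 23 and 1453 CPM in HFD Vehicle 50, and at 60.6 to 465 CPM in the remaining libraries. The transcript CT010467.1, which was chosen after its values were seen, took 13%, 1.03% and 2.72% of the counts of HFD 4, 30 and 38 and 0.0127% to 0.0246% of those of the Chow libraries. The table of HFD Vehicle and HFD PCN does not list it, so its level there is not known.

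**Figure D1:**
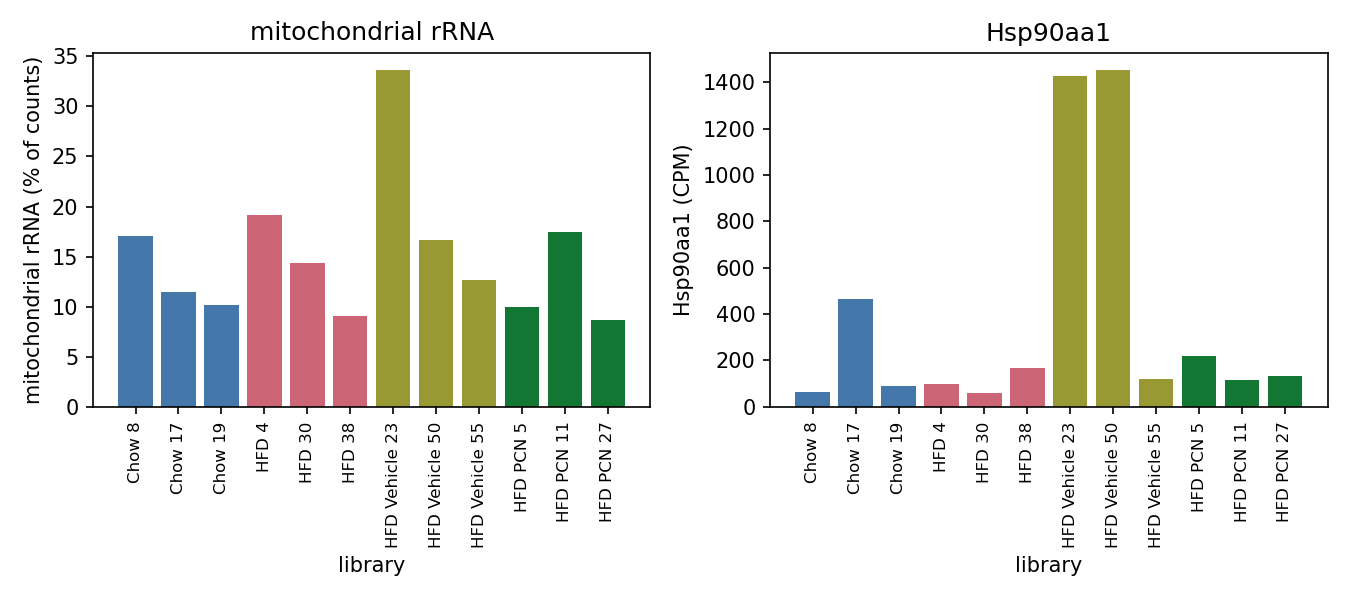
Bars show, for each of the 12 libraries on the x axis coloured by group, the share of counts in mitochondrial ribosomal RNA (left, percent) and the Hsp90aa1 level (right, CPM). HFD Vehicle 23 stands highest on the left at 33.6%, and HFD Vehicle 23 and 50 stand highest on the right at 1427 and 1453 CPM.

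The first comparison asked what the high-fat diet changed in the duodenum. Of the Cyp2c family of cytochrome P450 enzymes, which oxidise drugs and fatty acids, Cyp2c29, Cyp2c55 and Cyp2c66 were lower on the diet. Cyp2c29 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713) fell from 132 ± 23.0 to 7.13 ± 3.25 CPM (SD, n = 3 per group), a log2 fold change of -4.12 with an SE of 0.29. Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693) fell from 61.2 ± 8.50 to 7.08 ± 0.243 CPM, a log2 fold change of -3.10 with an SE of 0.17. Cyp2c66 (ENSMUSG00000067229, chromosome 19, 39113898 to 39187072) fell from 135 ± 3.51 to 61.0 ± 2.38 CPM. The antimicrobial lectin Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) fell from 680 ± 339 to 70.5 ± 11.4 CPM.

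The apolipoprotein L gene Apol10a (ENSMUSG00000050982, chromosome 15, 77477047 to 77491069) fell from 73.3 ± 23.8 to 20.2 ± 1.12 CPM, and the glutathione transferase Gstm1 (ENSMUSG00000058135, chromosome 3, 108012255 to 108017973) fell from 78.6 ± 8.04 to 37.4 ± 1.94 CPM. Siglec1 (ENSMUSG00000027322, chromosome 2, 131069220 to 131086765), a sialic acid binding lectin of macrophages, rose from 2.79 ± 0.236 to 9.16 ± 1.56 CPM. By edgeR's quasi-likelihood test, 10 of 15278 genes passed, 1 higher and 9 lower, with adjusted p of 2.61e-05 for Cyp2c55, 0.000421 for Cyp2c29, 0.0199 for Apol10a and Cyp2c66, 0.0257 for Reg3b, 0.0399 for Gstm1 and 0.0481 for Siglec1. The other called genes, outside the rule and chosen after their values were seen, were Mptx2 (log2 fold change -5.59), the mucosal pentraxin, and the immunoglobulin segments Igkv4-55 (-2.42) and Ighv3-6 (-1.95). Mptx2 had a mean count of 17.7 and stood at 0.0978 ± 0.123 CPM on HFD, so the size of its fold change rests on very few reads. The authors' deposited table gave it -1.59. At an unadjusted p under 0.05 there were 1581 genes, against 764 that chance would give, and the groups did not overlap for 16.3% of genes, against 10% by chance. The authors' deposited table had 106 genes past the threshold, and all 10 genes called here were among them with the same direction. Each had a smaller log2 fold change there, such as -3.24 for Cyp2c29, where DESeq2 run here gave -4.14. How the deposited values were estimated is not known in detail, so their sizes should not be compared directly with those here. DESeq2 called 134 genes (56 higher, 78 lower) and limma-voom 6. Cyp2c and Gstm genes and immunoglobulin segments belong to families whose members can share reads, so their separate values are uncertain.

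Cyp2c55 and Cyp2c29 passed without any one of the 6 libraries, but in the fit of all 12 libraries the adjusted p of edgeR's test was 0.249 for Cyp2c55 and 0.0182 for Cyp2c29, each the highest over its alternatives, and 2 genes passed (Cyp2c29 and Apol10a). Cyp2c66 was not called without Chow 8, 17 or 19 or HFD 30, Reg3b without Chow 8 or HFD 4 or 30, Apol10a without HFD 4 or 30, and Gstm1 and Siglec1 without any one of Chow 8, 17 and 19 and HFD 4 and 30. The count was 4 without Chow 8, 6 without Chow 19, 5 without HFD 30 and 63 without HFD 38. It was 7 without Chow 17 and 8 without HFD 4, of which 4 and 3 were among the 10.

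The list of PXR targets and drug metabolism genes had 26 measured members, of which 21 had negative fold changes and 3 (Cyp2c55, Cyp2c29 and Cyp2c66) fell by the test over all genes, or 9 adjusted over the list alone. Its mean log2 fold change was -0.77, with a camera adjusted p of 5.56e-23 (adjusted p = 0.313 with an estimated correlation). Cyp3a11, the main CYP3A drug oxidase of the mouse and a standard PXR target, had 1932 ± 414 CPM on chow and 566 ± 167 CPM on HFD (log2 fold change -1.77, SE 0.28, edgeR adjusted p = 0.0611). Cyp2b10, a target of the constitutive androstane receptor, had a log2 fold change of -1.14 (SE 0.21, edgeR adjusted p = 0.118). In the authors' deposited table, Cyp3a11 had a log2 fold change of -1.46 (adjusted p 2.05e-08) and Cyp2b10 one of -0.99 (adjusted p 0.000243). The receptor genes themselves, Nr1i2 (PXR) and Nr1i3, had log2 fold changes of 0.30 (SE 0.19) and 0.30 (SE 0.24) with edgeR adjusted p of 0.587 and 0.657. Phase II conjugation enzymes had a mean of -0.17 over 35 members, with Gstm1 lower and 4 lower adjusted over the list alone (camera adjusted p 0.000913, adjusted p = 0.541 with an estimated correlation). That list was not called without HFD 4. Markers of mature enterocytes, the cells that express these enzymes, had a mean of -0.19 (camera adjusted p 0.0732), with 0 called by edgeR over all genes and 2 lower adjusted over the list alone. In mean log2 CPM that enterocyte list differed by -0.42 (SE 0.52), and by 0.084 (SE 0.22) without HFD 4.

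Markers of T and NK cells, the lymphocytes of the gut wall, had negative fold changes for 16 of 17 members with a mean of -1.01. No member passed over all genes and 12 were lower adjusted over the list alone (camera adjusted p 2.57e-15, adjusted p = 0.313 with an estimated correlation). Trdc, the constant segment of the T cell receptor delta chain, had a log2 fold change of -1.95 (SE 0.40), and Gzmb, which encodes granzyme B, one of -1.39 (SE 0.29). Genes of MHC class II antigen presentation had a mean of -0.57 over 10 members, with 0 called over all genes and 4 lower adjusted over the list alone (camera adjusted p 0.000125, adjusted p = 0.625 with an estimated correlation), and Cd74, the invariant chain, stood at 468 ± 217 CPM on chow and 196 ± 48.9 CPM on HFD. The antimicrobial and mucosal defence list had a mean of -0.74 over 10 members, with Reg3b called and 3 lower adjusted over the list alone (camera adjusted p 5.89e-05, adjusted p = 0.313 with an estimated correlation). Myeloid markers went the other way, with a mean of 0.46 over 14 members and 3 higher adjusted over the list alone (camera adjusted p 0.000135, adjusted p = 0.541 with an estimated correlation). Among them Cx3cr1, the fractalkine receptor, stood at 3.27 ± 0.0875 CPM on chow and 7.87 ± 0.676 CPM on HFD.

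Genes of peptide digestion and amino acid transport had negative fold changes for 19 of 20 members with a mean of -0.66, and 7 were lower adjusted over the list alone (camera adjusted p 8.57e-12, adjusted p = 0.503 with an estimated correlation). Enpep, glutamyl aminopeptidase, had a log2 fold change of -1.28 (SE 0.33) and the proline transporter Slc6a20a one of -1.05 (SE 0.24). Nuclear genes of oxidative phosphorylation had positive fold changes for 27 of 29 members with a mean of 0.27 and 0 called over all genes or adjusted over the list alone (camera adjusted p 5.46e-05, adjusted p = 0.660 with an estimated correlation), a call lost without HFD 38. Pancreatic acinar markers, which could come from pancreas attached to the duodenum, had negative fold changes for 18 of 19 members, with 11 lower adjusted over the list alone (camera adjusted p 6.61e-15, adjusted p = 0.503 with an estimated correlation). Their elastase genes Cela1 and Cela3b had log2 fold changes of -1.51 (SE 0.33) and -3.39 (SE 0.64), and the list took 0.0545% to 0.139% of the counts of the 12 libraries. Cela3b stood at 0.271 ± 0.375 CPM on HFD, so the size of its fold change rests on few reads. In all, 18 of 40 tested lists were called by camera, 7 higher and 11 lower, and 0 with an estimated correlation or by fry, whose lowest adjusted p were 0.313 and 0.117.

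The second comparison asked what PCN changed against vehicle in mice that the labels' protocols call obese. PCN raised enzymes of drug and ester metabolism. Cyp2c55 rose 72.4-fold, from 5.22 ± 2.22 to 366 ± 252 CPM (SD, n = 3 per group), a log2 fold change of 6.18 with an SE of 0.74. Cyp2c29 rose 42.9-fold, from 20.5 ± 3.56 to 879 ± 585 CPM. Among the carboxylesterases, which cleave drug and lipid esters, Ces2a (ENSMUSG00000055730, chromosome 8, 104734003 to 104741634) rose from 87.7 ± 19.5 to 1248 ± 487 CPM. Ces2b (ENSMUSG00000050097, chromosome 8, 104831572 to 104840093) rose from 2.04 ± 1.58 to 50.3 ± 26.4 CPM. The microsomal epoxide hydrolase Ephx1 (ENSMUSG00000038776, chromosome 1, 180976210 to 181020904) rose from 12.8 ± 5.42 to 173 ± 66.0 CPM.

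Cyp2c66 rose from 68.1 ± 18.1 to 486 ± 205 CPM and Gstm1 from 36.7 ± 15.7 to 347 ± 163 CPM after PCN. Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), which encodes the mitochondrial leucyl-tRNA synthetase, fell from 212 ± 108 to 31.6 ± 4.38 CPM. As Lars2 holds sequence that resembles ribosomal RNA, its fall may reflect such RNA carried into the libraries. By edgeR's quasi-likelihood test 10 of 16110 genes passed, 8 higher and 2 lower, with adjusted p of 0.0165 for Ces2a, 0.0227 for Cyp2c29, 0.0255 for Ephx1, 0.0432 for Ces2b, Cyp2c66, Cyp2c55 and Lars2, and 0.0494 for Gstm1. The other called genes, outside the rule and chosen after their values were seen, were the immunoglobulin segment Igkv8-21 (log2 fold change 3.61) and the antisense gene Gm15564 (-4.85), whose reads cannot be told from those of the opposite strand where the counting did not use strand. Ces2, Cyp2c and Gstm genes are multigene families, and reads shared between their members leave the separate values uncertain. At an unadjusted p under 0.05 there were 2887 genes, against 806 by chance, and the groups did not overlap for 19.3% of genes, against 10% by chance. The authors' deposited table had 216 genes past the threshold, with all 10 among them in the same direction, each again with a smaller log2 fold change. DESeq2 called 339 genes, 107 higher and 232 lower.

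No gene passed edgeR's test without HFD PCN 11 or without HFD Vehicle 50, while 5 passed without HFD Vehicle 23, 4 of them among the 10 (Cyp2c29, Cyp2c55, Cyp2c66, Ces2b and Gstm1 were among those lost), and 3697 without HFD Vehicle 55. Without HFD Vehicle 23 and 50 together, 2 genes passed, 1 of them (Lars2) among the 10, while the log2 fold changes were 3.62 for Ces2a, 5.37 for Cyp2c29, 5.63 for Cyp2c55 and 3.70 for Ces2b, the last against 4.84 with all 6 libraries. Against untreated HFD 52 genes passed, 39 higher and 13 lower, 5 of them among the 10. Ces2b, at 2.82 (SE 0.51), was only one of the genes among the 10 that were not called there. Library quality weights gave 4453, with weights of 2.47 for HFD Vehicle 50, 0.307 for HFD Vehicle 23 and 0.483 for HFD Vehicle 55. The vehicle group of that fit thus rested mostly on HFD Vehicle 50, a library high in Hsp90aa1. Leaving out genes that resemble ribosomal RNA gave 4, of which Ces2a, Ces2b, Cyp2c29 and Ephx1 were all higher. Calls of single genes were also lost without HFD PCN 5 for Cyp2c55, Cyp2c66, Gstm1 and Lars2, and without HFD PCN 27 for Lars2, with 7 and 11 genes passing.

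**Figure D2:**
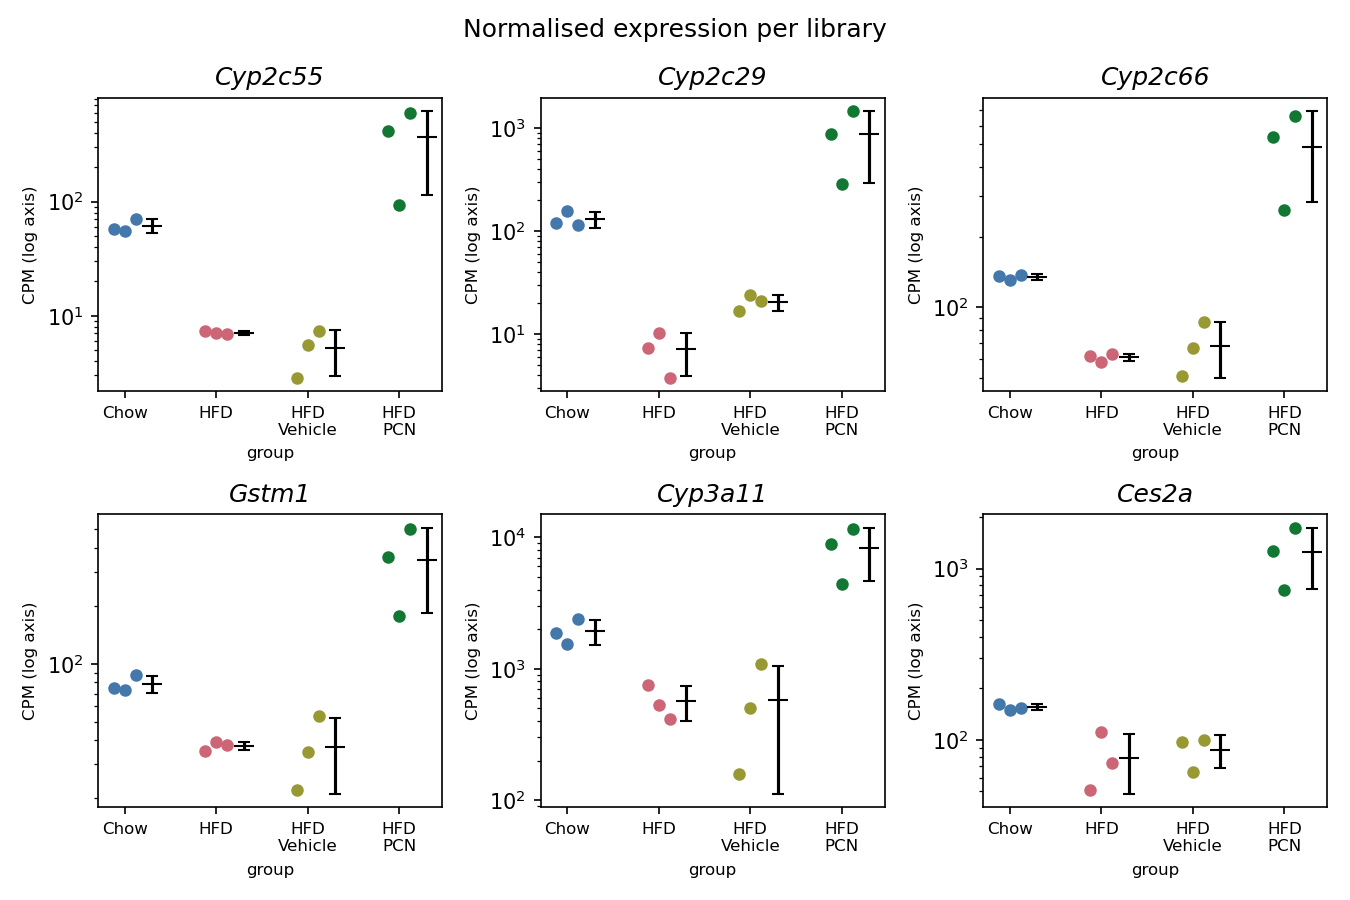
Points show CPM on a log axis for each of 3 libraries per group (x axis, the 4 groups), with the mean and SD in black, for Cyp2c55, Cyp2c29, Cyp2c66, Gstm1, Cyp3a11 and Ces2a. CPM of Chow and HFD and those of HFD Vehicle and HFD PCN were scaled in separate fits. Cyp2c55 had means of 61.2 CPM in Chow, 7.08 in HFD, 5.22 in HFD Vehicle and 366 in HFD PCN.

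All 26 measured members of the PXR target list had positive fold changes after PCN, and the mean was 1.98. Cyp2c55, Cyp2c29, Cyp2c66, Ces2a and Ces2b rose by the test over all genes, and 19 members rose adjusted over the list alone (camera adjusted p 4.93e-32, adjusted p = 0.600 with an estimated correlation). Cyp3a11 stood at 582 ± 471 CPM after vehicle and 8259 ± 3584 CPM after PCN (log2 fold change 3.83, SE 0.71, edgeR adjusted p = 0.200), without overlap between the groups. Its log2 fold change was 4.66 without HFD Vehicle 55, where it passed, as Cyp2b10 did, and 2.90 without HFD Vehicle 23 and 50, where it did not. Over its alternatives the adjusted p of Cyp3a11 ranged from 0.000268 with DESeq2 to 0.715. In the authors' deposited table its log2 fold change was 2.80 (adjusted p 1.12e-08). Cyp2b10 had a log2 fold change of 1.42 (SE 0.33, edgeR adjusted p = 0.231). Nr1i2 stood at 156 ± 11.4 and 170 ± 20.9 CPM (log2 fold change 0.12, SE 0.20, edgeR adjusted p = 0.746).

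Phase II conjugation enzymes had positive fold changes for 34 of 35 members with a mean of 1.09. Gstm1 rose over all genes and 17 members rose adjusted over the list alone (camera adjusted p 4.17e-20, adjusted p = 0.600 with an estimated correlation). Among the transporters of drugs and bile acids, with a mean of 0.34 over 17 members and 1 higher adjusted over the list alone (camera adjusted p 0.0204, adjusted p = 0.600 with an estimated correlation), Abcb1a, the P-glycoprotein drug exporter, stood at 379 ± 62.4 and 959 ± 298 CPM (log2 fold change 1.34, SE 0.31, edgeR adjusted p = 0.231, passing without HFD Vehicle 55). The authors' deposited table gave it 1.23 (adjusted p 0.00239). The bile acid exporter subunit Slc51b had a log2 fold change of 1.58 (SE 0.51).

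Paneth cell markers, the antimicrobial products of the crypt base, had negative fold changes for 14 of 14 members with a median of -2.11. No member passed over all genes, and 12 fell adjusted over the list alone (camera adjusted p 4.00e-11, adjusted p = 0.600 with an estimated correlation). The defensin genes Defa17 and Defa23, members of a family that shares reads, had log2 fold changes of -3.15 (SE 0.61) and -2.73 (SE 0.59). They stood at 2.92 and 0.877 CPM after vehicle and 0.312 and 0.117 CPM after PCN, so these sizes rest on few reads. Against untreated HFD the list had a mean of -0.14 over 10 members (camera adjusted p 0.738). Pancreatic acinar markers had 17 of 19 negative fold changes, with 3 lower adjusted over the list alone (camera adjusted p 6.00e-05, adjusted p = 0.645 with an estimated correlation), a call lost without HFD Vehicle 23 and 50 and against untreated HFD. Fibroblast markers had a mean of -0.66 over 11 members, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p 0.000493, adjusted p = 0.600 with an estimated correlation). The type I collagen genes Col1a1 and Col1a2 had log2 fold changes of -1.66 (SE 0.41) and -1.23 (SE 0.30). Smooth muscle markers were negative for 12 of 12 members with 0 called over all genes or adjusted over the list alone (camera adjusted p 0.000254, adjusted p = 0.645 with an estimated correlation).

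Some metabolic lists were higher after PCN by camera, while fatty acid synthesis (mean 0.077, 7 of 19 members positive, 3 higher adjusted over the list alone), oxidative phosphorylation (camera adjusted p 0.239) and carbohydrate digestion (0.208) were not called. Genes of fatty acid oxidation and ketogenesis had positive fold changes for 34 of 38 members with a mean of 0.39 (camera adjusted p 7.41e-05, adjusted p = 0.645 with an estimated correlation). The rate-limiting carnitine palmitoyltransferase Cpt1a had a log2 fold change of 0.65 (SE 0.29). Cholesterol synthesis genes had a mean of 0.29 over 26 members (camera adjusted p 0.00231, adjusted p = 0.600 with an estimated correlation). Idi1, which isomerises isopentenyl diphosphate, had a log2 fold change of 0.98 (SE 0.28). Genes of sterol uptake and efflux had a mean of 0.35 over 18 members (camera adjusted p 0.00326, adjusted p = 0.645 with an estimated correlation), with Npc1l1, the intestinal cholesterol importer, at 0.66 (SE 0.27) and the exporter Abca1 at 1.04 (SE 0.27). No member of these 3 lists passed over all genes or adjusted over the list alone. Mature enterocyte markers were positive for 16 of 16 members with a mean of 0.60 and 0 passing either way (camera adjusted p 0.000310, adjusted p = 0.645 with an estimated correlation), and T and NK cell markers were positive for 16 of 17 with a mean of 0.89 and 0 passing either way (camera adjusted p 7.41e-05, adjusted p = 0.645 with an estimated correlation).

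In all, 20 of 42 tested lists were called by camera in the PCN comparison, 14 higher and 6 lower, and 0 with an estimated correlation or by fry. The lowest adjusted p of these were 0.600 and 0.327. Without HFD Vehicle 23 and 50, 19 lists were called, 9 of them among the 20. The fatty acid oxidation, enterocyte, T and NK cell and smooth muscle calls were lost, and those of the PXR, phase II, Paneth, fibroblast, cholesterol synthesis, sterol uptake and transporter lists held. Against untreated HFD 19 lists were called, 13 of them among the 20, and the Paneth, acinar, smooth muscle and sterol uptake calls were lost. With an estimated correlation 0 lists were called there either (lowest adjusted p 0.290).

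**Figure D3:**
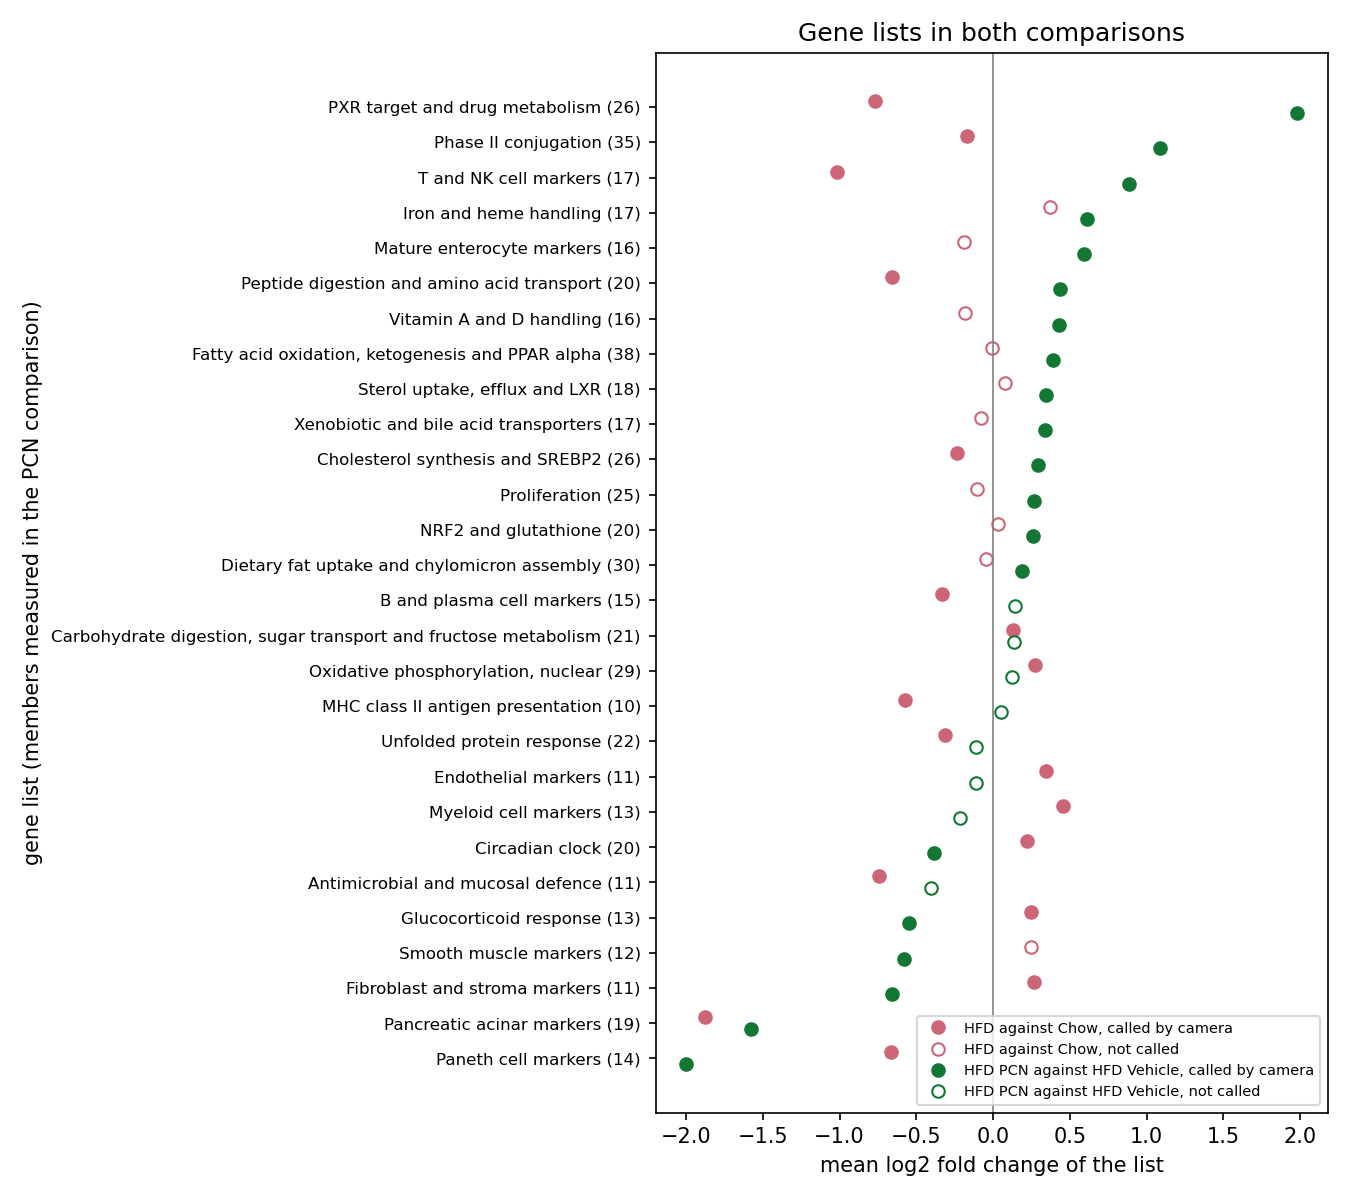
Each point is the mean log2 fold change (x axis) of a gene list (y axis, with the members measured in the PCN comparison) in HFD against Chow or in HFD PCN against HFD Vehicle. Filled points are lists called by camera at its preset correlation, none of which held with an estimated one. The PXR target list has means of -0.77 on the diet and 1.98 after PCN.

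The design allowed the diet genes to be looked up in the PCN comparison, which shares no library with the diet comparison. Cyp2c55, Cyp2c29, Cyp2c66 and Gstm1 fell on the diet and rose after PCN. Of the 9 genes lower on the diet, 6 had positive fold changes after PCN, with a mean log2 fold change of 1.89 (limma's fry, two-sided, unadjusted p 0.0243 in the 1 set tested). Without the immunoglobulin segments the mean was 2.02 over 7 genes (limma's fry, p 0.0419), of which 4 were positive, namely Cyp2c55, Cyp2c29, Cyp2c66 and Gstm1. The others had log2 fold changes of -0.75 (SE 0.92) for Reg3b, -0.53 (SE 0.25) for Apol10a and -2.26 (SE 0.96) for Mptx2, so the 4 enzymes carry the mean. The mean was 0.978 without HFD PCN 5, 1.98 without HFD PCN 11, 1.67 without HFD Vehicle 23 and 1.76 without HFD Vehicle 50, with fry p of 0.0716, 0.0851, 0.0789 and 0.0764. Without HFD Vehicle 23 and 50 together it was 1.42, with a fry p of 0.298.

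Across 15121 genes, which are not independent replicates, the fold changes of the comparisons had a Pearson correlation of -0.263 and a Spearman correlation of -0.311. At an unadjusted p under 0.05, 124 genes were lower on the diet and higher after PCN, against 44.8 for independent lists, and 211 were higher on the diet and lower after PCN, against 95.7. Genes moving the same way numbered 22 lower in both, against 75.2, and 22 higher in both, against 57.0. HFD 4 and HFD Vehicle 23 and 50 lay apart from the other libraries on the first principal component (-33.4, -92.2 and -44.1, the others 0.942 or above), and they stand in the treated group of the diet comparison and the control group of the PCN comparison. Without HFD 4 the correlations were -0.0967 and -0.116, with 93 genes lower then higher, against 52.4, and 113 higher then lower, against 127. Without all 3 they were -0.125 and -0.146, with 36 genes against 12.6 and 58 against 21.7. These choices of libraries were made after the values were seen. Leaving out any single library but HFD PCN 27 moved 1 or both counts by over 1.5 times, to 48 (HFD PCN 5, against 14.5) up to 244 (HFD Vehicle 55, against 127) and to 75 (Chow 19, against 38.5) up to 397 (HFD 38, against 129). By the authors' deposited columns, 15 genes were lower on the diet and higher after PCN, against 0.184 for independent lists, 0 higher then lower, against 0.214, 1 lower in both, against 0.348, and 0 higher in both, against 0.113. Cyp2c55, Cyp2c29, Cyp2c66 and Gstm1 are among the genes lower on the diet and higher after PCN by these columns.

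The third comparison set HFD Vehicle against untreated HFD, to see what injection and vehicle went with. The squalene synthase gene Fdft1 stood at 14.4 ± 1.59 CPM in HFD and 29.3 ± 7.19 CPM in HFD Vehicle (SD, n = 3 per group, log2 fold change 1.03, SE 0.25). Chga, which encodes the chromogranin A of hormone granules, stood at 33.9 ± 1.84 and 66.5 ± 21.8 CPM (log2 fold change 0.97, SE 0.27). The core clock gene Arntl stood at 17.5 ± 3.14 and 9.21 ± 2.25 CPM (log2 fold change -0.94, SE 0.27). Cyp3a11 stood at 546 ± 168 and 591 ± 477 CPM and Abcb1a at 235 ± 111 and 385 ± 61.5 CPM. No gene of 16255 passed edgeR's quasi-likelihood test, with 953 at an unadjusted p under 0.05 against 813 by chance, and Fdft1, Chga and Arntl each had an adjusted p of 0.803. DESeq2 called 32 genes and limma-voom 0, and the groups did not overlap for 9.92% of genes, against 10% by chance. Without HFD Vehicle 55, edgeR called 260 genes.

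Paneth cell markers were positive in HFD Vehicle against HFD for 13 of 13 members with a mean of 1.90, and 10 were higher adjusted over the list alone (camera adjusted p 1.18e-15, adjusted p = 0.841 with an estimated correlation). Defa21 and Defa23 had log2 fold changes of 3.64 (SE 0.83) and 3.03 (SE 0.66). At 0.318 and 0.131 CPM in HFD, the sizes of these changes rest on few reads. The mean log2 CPM of the Paneth list was 5.07 in HFD Vehicle 23 and 4.03 in HFD Vehicle 50, the libraries high in Hsp90aa1, against 3.03 in HFD Vehicle 55 and 2.65, 1.48 and 2.48 in HFD 4, 30 and 38. The HFD Vehicle libraries also enter the PCN comparison, with the opposite sign, so the values of this list in both are not independent. Cholesterol synthesis genes had a mean of 0.42 over 26 members (camera adjusted p 1.15e-05, adjusted p = 0.841 with an estimated correlation), enteroendocrine markers one of 0.54 over 17 (camera adjusted p 1.20e-05, adjusted p = 0.841 with an estimated correlation), and interferon response genes one of -0.70 over 30 (camera adjusted p 6.45e-06, adjusted p = 0.890 with an estimated correlation). These 3 lists had 0 members passing edgeR over all genes or adjusted over the list alone, and the interferon call was lost without HFD 30 and the enteroendocrine call without HFD Vehicle 55. Acinar markers were positive for 18 of 20 members (camera adjusted p 1.46e-06, adjusted p = 0.841 with an estimated correlation). The PXR target list had a mean of -0.01 over 26 members and a camera adjusted p of 0.829, with 1 member higher adjusted over the list alone. In all, 13 of 42 lists were called, 7 higher and 6 lower, with 22 called without HFD 4 and 8 without HFD 30. With an estimated correlation or by fry 0 were called, with lowest adjusted p of 0.841 and 0.779.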

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

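Quality weights, leaving out ribosomal RNA-like genes and leaving out HFD Vehicle 23 and 50 were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Other size factors, the filter at 1 CPM, the 1.5-fold minimum and leaving out the acinar list kept each count of genes within 1.5 times. The diet count of 10 became 351 with no filter, 134 with DESeq2, 6 with limma-voom, 2 in the fit of 12 libraries, 16 with quality weights, and 4 (without Chow 8) to 63 (without HFD 38) with 1 library left out. The PCN count of 10 became 843, 339, 34 (all 12), 4 (ribosomal RNA-like genes out), 4453 (quality weights), 2 (without HFD Vehicle 23 and 50), 52 (untreated HFD as control), and 0 (without HFD PCN 11 or HFD Vehicle 50) to 3697 (without HFD Vehicle 55). The vehicle count of 0 became 1 with no filter, 32 with DESeq2 and 1 in the fit of 12, and 0 to 260 (without HFD Vehicle 55), with 953 genes at an unadjusted p under 0.05. The cause of these moves was not tested. Fewer libraries leave fewer degrees of freedom, yet the PCN and vehicle counts rose without HFD Vehicle 55. On the first principal component HFD Vehicle 55 lay at 23.2, and HFD Vehicle 23 and 50, which then remain, at -92.2 and -44.1. Without HFD Vehicle 23 and 50 the lone vehicle library was assumed to vary like the PCN group, and the ribosomal RNA-like genes left out include Lars2 and Gm15564. With an estimated correlation 0 lists were called in each comparison. With 1 library left out the lists numbered 16 to 22 (diet), 19 to 23 (PCN) and 8 (without HFD 30) to 22 (without HFD 4, vehicle).

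The mean of the diet genes after PCN ranged from 0.978 (without HFD PCN 5) to 2.64 (without HFD Vehicle 55) and was 1.42 without HFD Vehicle 23 and 50. The signs of some uncalled log2 fold changes turned. After PCN these were Hmox1 (1.25) and Slc38a2 (0.0048) without HFD Vehicle 23 and 50, and Nr1i2 -0.020 and Nr1i3 -0.084 against untreated HFD. In the vehicle comparison Cyp3a11 became -0.10 with limma-voom, -0.048 with quality weights, -0.065 without HFD 4 and -0.73 (without HFD Vehicle 55) to 0.57 (without HFD Vehicle 23). Npc1l1 became 0.15 with quality weights and -0.35 (without HFD Vehicle 50) to 0.11 (without HFD 30). The proliferation list turned to a mean of -0.030 without HFD Vehicle 23 and 50. The camera direction of the clock list (mean -0.014) turned against untreated HFD and that of the fatty acid oxidation list (mean -0.024, and -0.37 without HFD Vehicle 55) turned without HFD Vehicle 23 in the vehicle comparison, while both means kept their sign. Over the named genes, 70 further values lost the threshold and 161 reached it, and 110 list calls were lost. At the depth of 4676718 counts in HFD Vehicle 55, changes in genes of a few counts could not be resolved. Without scaling, the median log2 fold change was -0.148 (diet), 0.0617 (PCN) and -0.105 (vehicle), against 0.00459, -0.0121 and 0.00757 with TMM.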

Other observations

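Heat shock genes, chosen after their values were seen, set HFD Vehicle 23 and 50 apart. Hsph1, a chaperone of the HSP110 family, stood at 3194 and 3464 CPM in them and at 34.2 to 89.5 CPM in the other libraries of the PCN comparison. Bag3, a co-chaperone, stood at 292 and 307 CPM against 22.5 to 62.9 CPM in the remaining 10 libraries, and the mitochondrial chaperone Hspd1 at 807 and 720 CPM. In HFD PCN against HFD Vehicle, Dnajb1 had a log2 fold change of -4.48 (SE 1.33) and Hspb1 one of -3.76 (SE 1.07), both with an edgeR adjusted p of 0.240. HFD Vehicle 55, of the same group, had 34.2 CPM of Hsph1 and 24.6 CPM of Bag3.

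With untreated HFD as the control, further PXR genes were higher after PCN by edgeR's test. Cyp3a11 had a log2 fold change of 3.95 (SE 0.43, n = 3 per group) and Abcb1a, the P-glycoprotein, one of 2.05 (SE 0.36), and both passed. In the PXR list 26 of 26 members were positive with a mean of 1.96, and 10 passed over all genes and 22 adjusted over the list alone. This contrast compares injected with uninjected mice, and its camera test was chosen after the data were seen.

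The tests in this and the following paragraphs that use list scores, ribosomal RNA references or DESeq2 genes were chosen after related results were seen, and only the counts over splits were planned. The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real diet split called 10 genes and the highest other 1 (number as large: 1), the PCN split 10 and 2 (1), and the vehicle split 0 and 100 (10 of 10). The split with 100 sets HFD 4, HFD Vehicle 23 and HFD Vehicle 50 against the rest, which points to a structure of the samples. For lists the real values were 18, 20 and 13 with the highest other 21, 27 and 27, and 4, 4 and 8 splits were as large. For the diet genes after PCN they were 1.89 and 1.15 (1).

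By camera at its preset correlation the PXR target list was lower on the diet and higher after PCN. With an estimated correlation camera called neither (adjusted p = 0.313 and 0.600). A smaller or larger share of mature enterocytes could account for either. After PCN the list minus the enterocyte list, in mean log2 CPM, rose by 1.24 (SE 0.216) and the list against untreated HFD by 1.97 (SE 0.349), which argues against the enterocyte share or the state of the HFD Vehicle libraries as the whole cause. On the diet the list minus the enterocyte list differed by -0.402 (SE 0.281), and the enterocyte list itself by -0.42 (SE 0.52). HFD 4 carried the lower enterocyte value: without it the differences were -0.66 (SE 0.13) and 0.084 (SE 0.22), while without HFD 38 they were -0.22 (SE 0.35) and -0.78 (SE 0.65). Since the result turns on single HFD libraries, a change of cell share and a change within cells cannot be told apart on the diet. The condition for the enterocyte share as cause was tightened after a first version had passed it, by also asking that the enterocyte list itself move.

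Lars2 and Gm15564 were lower after PCN, and ribosomal RNA carried into the HFD Vehicle libraries may account for them, as Lars2 is known to hold sequence that resembles ribosomal RNA. In log2 CPM, Lars2 differed by -2.63 (SE 0.438), Gm26917 by -2.70 (SE 1.08) and Gm42418 by -3.62 (SE 0.813). Gm42418 was a second ribosomal reference, added after the first was seen. The log2 ratio of Lars2 differed by 0.0726 (SE 0.671) against Gm26917 and by 0.986 (SE 0.416) against Gm42418. Lars2 thus showed no fall beyond that of either reference. As the references differ, whether carry-over alone accounts for Lars2 stays open. Over the 12 libraries log2 CPM of Lars2 and Gm26917 had a Pearson r of 0.920 and a Spearman rho of 0.902 (permutation p 4e-05 and 2e-04, the same after adjustment over 2 relations), with r 0.883 without HFD Vehicle 23 and 50 and 0.849 within groups. For Gm42418 r was 0.972 and rho 0.965 (permutation p 1e-05, the smallest that 100000 resamples give, adjusted 2e-05), with r 0.965 without HFD Vehicle 23 and HFD PCN 5 and 0.919 within groups. The ratio of Gm15564 differed by -2.21 (SE 0.951) and -1.30 (SE 0.545), below both references. Gm15564 was picked for its fall in these same libraries, with 3 per group. The ratios therefore cannot decide whether a carry-over in fixed proportion was its whole cause, and no biological explanation was tested.

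Genes lower after PCN may reflect the state of the HFD Vehicle libraries. The Paneth list differed by -1.75 (SE 0.65) from vehicle and by 0.0926 (SE 0.462) from untreated HFD, as a state of those libraries would give. An effect of injection that PCN undid would give the same, and the design does not separate them. Untreated HFD itself differed from Chow by -0.915 (SE 0.429) on the Paneth list. HFD Vehicle 55, without high heat shock levels, stood at 3.03 on it, against 1.90 to 2.84 in the HFD PCN libraries. The 232 genes lower by DESeq2 had a median log2 fold change of -1.85 against vehicle and -0.907 against untreated HFD over 176 measured, with an interquartile range of -1.29 to -0.53 that spans the bound of -0.923, at 50% of the first median. Without HFD Vehicle 23 and 50 the median was -0.58, and in HFD Vehicle against HFD, which shares libraries with both, 0.85. For the 107 higher genes these medians were 1.10 and -0.30. These genes were chosen in a fit that holds those libraries, so a loss of size without them can come from the choice itself. A share due to the vehicle libraries and one due to PCN cannot be told apart, since the genes spread across the bound. The margin of that bound was added after the value was seen, since the 49.2% kept lay just under the 50% first written, while the higher genes kept 76.0%.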
